A study of Macaca fascicularis with 16 samples.

How the data were processed

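Nuclear RNA of the frontal cortex of cynomolgus monkeys was measured by droplet single-nucleus RNA sequencing with 10x Genomics 3' v3 chemistry. There were 16 libraries, each from a separate animal per the labels, in 4 groups of 4: the control antibody anti-gD at 200 mg/kg on day 3, Para09 at 50 mg/kg on day 3, Para09 at 200 mg/kg on day 3 and Para09 at 50 mg/kg on day 29. Per the labels' protocols, frozen tissue was lysed and homogenised without thawing, and nuclei were collected from a density gradient. Only RNA held in or attached to nuclei was therefore counted, so a transcript that sits mostly in the cytoplasm was sampled thinly. The series text describes injection into the spinal fluid and collection after 2 days, while the labels give doses per body weight and days 3 and 29; the groups used here follow the labels.

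The authors deposited raw UMI counts per gene and nucleus in a filtered matrix for each library, per the file headers. The submitters' processing notes name Cell Ranger 3.1.0 and Seurat 3.1.1 without their roles. The genome build and the annotation release were not given in the sources used here, so no coordinates are printed. The matrices hold 29324 features with Ensembl gene identifiers. Of these, 8022 had no symbol and 4450 shared a symbol with another feature and were kept apart by identifier.

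The files held 120873 barcodes and 716435972 UMIs. Nuclei with at least 500 detected genes and under 5% of UMIs from mitochondrial genes were kept, which left 118246. Scrublet scores, as computed by scanpy 1.11.5, were ranked within each library, and the highest 0.8% per 1000 barcodes were removed as doublets, 9244 in all. The 109002 nuclei left were scaled to 10000 UMIs, log-transformed and reduced to 30 principal components of 3000 variable genes. A graph of 15 neighbours was clustered by Leiden (leidenalg 0.10.2) at resolution 1, which gave 45 clusters. Before the principal components were computed, each variable gene was scaled and centred on its mean in each library. No other batch correction was applied. Clusters were named from marker lists. A name needed at least 3 markers, each in at least 10% of the nuclei and at 20% or more of its CPM in the highest cluster of at least 200 nuclei. That level replaced an enrichment over other clusters after the first naming was seen, since the enrichment had left excitatory clusters unnamed. A cluster stayed unnamed where another type had more markers among its 10 leading genes, where a second type had 3 markers and 50% of its list, or where cilia genes led it, a reason added after the clusters were seen. The rule on a second type was waived between microglia and perivascular macrophages, and between mural cells and endothelial cells or fibroblasts. The microglia cluster held the macrophage markers MRC1, CD163 and STAB1, the macrophage cluster 8 microglia markers and the endothelial cluster 3 mural markers. Low depth with no leading marker would have left a cluster unnamed too. Of the clusters, 4 with 2035 nuclei stayed unnamed: 1 with 4 excitatory markers, led by genes with the oligodendrocyte marker ST18 among them, 1 with GFAP among leading mitochondrial genes, 1 with markers of oligodendrocytes and their precursors, and the cilia cluster. The cilia cluster, with 5 astrocyte markers, made up 0.156 ± 0.313% of nuclei in controls, 0.0411 ± 0.0564% at 50 mg/kg, 0% at 200 mg/kg and 0.192 ± 0.384% at day 29.

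Raw UMI counts were summed per library and cell type, leaving out libraries with under 10 nuclei of the type. These sums were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalization, genes kept by filterByExpr) under R 4.3.3. All 4 groups shared a fit per cell type, with group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are counts divided by the UMIs of the type in the library, in the usual CPM unit. Group means of tested genes and summed list levels in microglia carry the TMM factor and are relative to the UMIs of tested genes. Values of single genes in single libraries and list sums in excitatory neurons do not carry it. Neither do the list or marker sums that are compared with other types or with the mitochondrial share. Perivascular macrophage nuclei were too few for gene tests.

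Gene lists were tested with camera (limma 3.58.1) on the same fits with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 145 tests of list, cell type and comparison. Adjusted p-values with an estimated correlation, and those of fry, were computed beside them. The lists tested in microglia were homeostatic microglia, disease-associated microglia, lipid handling, cholesterol synthesis, inflammatory chemokines and cytokines, interferon response, proliferation, antigen presentation, TREM2 receptor signalling, Fc receptor and complement, lysosome and phagocytosis, growth and metabolism, border macrophage, and blood monocyte and lymphocyte. A reactive astrocyte list was tested in astrocytes, myelin and cholesterol synthesis lists in oligodendrocytes, and immediate early and heat shock lists in every type. These 18 lists held 344 different symbols, of which 44 were not in the feature names. A list needed 3 measured members. With 1 measured member in microglia (LYZ), the blood list had no test, and neither did the immediate early list there, with BTG2 and EGR1.

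Shares of nuclei and summed list levels were compared by exact two-sided permutation tests of the difference in means. With 4 against 4 there are 70 arrangements, and the smallest p is 0.0286. Benjamini-Hochberg adjustment ran over 32 share tests. The SD is given over animals, n = 4 per group unless stated.

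The lists, the markers, the comparisons, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 12 rising and 12 falling genes per microglia comparison (up to 4 and 4 in other types) with the largest fold among genes past the threshold with a symbol and a mean log2 CPM of at least 5. Where under 5 passed, it named the 5 with the smallest p. It also named up to 4 members of each list with the smallest p, and TREM2, TYROBP, CSF1R, P2RY12, APOE, SPP1, CD74 and MKI67 in every microglia comparison.

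The gene test was tested on simulated data drawn from the real means and library sizes, with 50 genes changed at each of 4 fold sizes. For microglia at 200 mg/kg against anti-gD, among 8769 genes in the step, it recovered 12% of genes changed 1.5-fold, 28% at 2-fold, 82% at 4-fold and 94% at 8-fold. It made 8 calls among 8573 unchanged genes. For the same fit in oligodendrocytes, with 9091 genes, it recovered 8%, 40%, 84% and 94%. In excitatory neurons, with 16726 genes, it recovered 4%, 34%, 66% and 82%. Changes of 2-fold or less were therefore mostly beyond the reach of the gene test at this depth. The simulation changed many genes at once, which eases the adjusted threshold, and drew the libraries as independent. Its recovery may therefore be too high for the real data. There, LILRA4 in microglia was not called by edgeR at 200 mg/kg against anti-gD, with a log2 difference of -2.37.

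The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, only the groups compared, no doublet removal, nuclei with at least 1000 genes, libraries with at least 50 nuclei of the type, no libraries numbered 4 in the labels, no genes over 5 times higher in other types, and each library left out in turn. Other denominators and member sets were tried for shares and list levels. The mitochondrial share as a covariate, and the list levels without ANLN or without RAD51B, were added after the data were seen. No pair of libraries of a group matched within sampling noise: the lowest chi-square per degree of freedom was 2.27 in microglia and 21.9 in excitatory neurons.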

Results

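Frontal cortex nuclei of 16 cynomolgus monkeys were profiled after dosing with Para09, an agonist antibody against the human form of the microglial receptor TREM2, or with the control antibody anti-gD. The 4 groups of 4 animals were anti-gD at 200 mg/kg on day 3, Para09 at 50 mg/kg on day 3, Para09 at 200 mg/kg on day 3, and Para09 at 50 mg/kg on day 29. The labels place no control animals at day 29. Libraries held from 873 nuclei (Para09 50 mg/kg day 3, number 4) to 13771 nuclei (anti-gD, number 1), and from 11127774 to 75379946 UMIs. The median per nucleus ran from 2004 to 9331 UMIs. The 4 libraries numbered 4 were the smallest, with 1482, 873, 2913 and 1775 nuclei.

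Most major cell classes of the cortex were recovered, but no cluster was named as mural cells. Excitatory neurons made up 45355 nuclei (41.6% of those kept), inhibitory neurons 19384 (17.8%), oligodendrocytes 14020 (12.9%), astrocytes 9304 (8.54%), microglia 8507 (7.80%) and oligodendrocyte precursors 7889 (7.24%). There were 1543 vascular nuclei, 878 perivascular macrophage nuclei and 87 lymphocyte nuclei. The vascular class joined 564 endothelial nuclei with fibroblast clusters of 493 and 486 nuclei, so it was mostly fibroblasts. Microglia, the cells that carry TREM2, contributed 24 to 1126 nuclei and 92856 to 1212906 UMIs per library. Their median depth was 1045 UMIs per nucleus, against 7603 in excitatory neurons.

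Para09 at 200 mg/kg was compared with anti-gD on day 3 to ask what a high dose of the TREM2 agonist did to microglia. PSTPIP2 (ENSMFAG00000037150), an adaptor protein of the myeloid cytoskeleton, rose from 7.39 ± 1.92 to 52.2 ± 17.5 CPM (SD, n = 4 in this and every group mean). Genes of the cell cycle were higher as a group, with 12 of 13 measured members above control and a median log2 difference of 1.36 (adjusted p = 0.571 with an estimated correlation). Genes for Fc receptors and complement were lower as a group, with all 10 measured members below control, and so were the genes of homeostatic microglia, with 12 of 13 below. Interferon response genes were higher as a group and antigen presentation genes were lower. With an estimated correlation each of these 4 lists had an adjusted p of 0.679.

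The PSTPIP2 difference was 2.73 on the log2 scale (SE 0.42, adjusted p = 0.0333), and all 4 treated libraries lay above all 4 controls. It was the only gene called by edgeR of 9010 tested in microglia, where 336 (3.73%) had an unadjusted p under 0.05 and DESeq2 called 2. With no differences 5% would be expected, so counts below that are no sign of further changes. The share was 6.22% in oligodendrocytes at day 29 against anti-gD and 0.69 to 4.91% in all other types and comparisons. The second gene called by DESeq2 was LILRA4 (ENSMFAG00000016124), a leukocyte receptor of a family of similar genes whose counts are therefore uncertain. It was at 8.29 ± 3.69 CPM against 44.6 ± 15.6 in controls, with a log2 difference of -2.37 (SE 0.42, adjusted p = 0.0954 by edgeR). The other genes with the smallest p did not pass the test (adjusted p = 0.729). They were PPARG, a nuclear receptor of lipid metabolism, at 0.94 (SE 0.209), the interferon-induced IFI44L at 1.26 (SE 0.289), and FHIT at 0.94 (SE 0.22). The PSTPIP2 call was lost without any one of the 4 anti-gD libraries, numbers 1, 2 and 3 of Para09 200 mg/kg, or numbers 2 and 4 of Para09 50 mg/kg day 3, with adjusted p from 0.00165 to 0.261 over the 16 single omissions. It was also lost with the mitochondrial share as a covariate, although the fold was then 2.70 (SE 0.431).

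**Figure D1:**
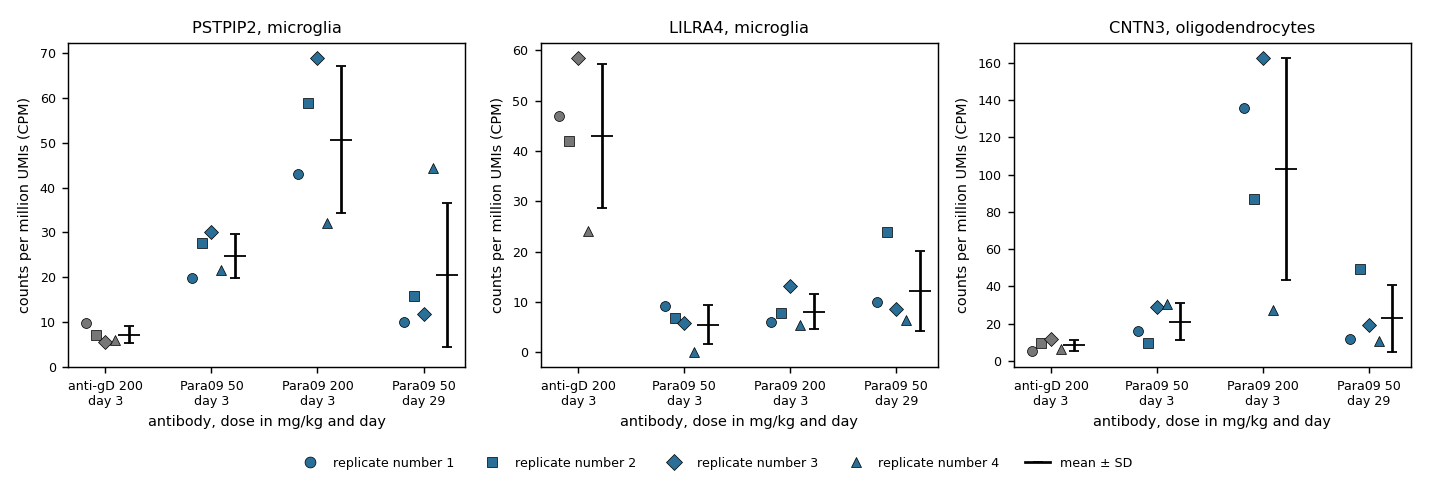
CPM of PSTPIP2 and LILRA4 in microglia and of CNTN3 in oligodendrocytes, with a point for each library, its shape set by the library's number, and bars for the group mean and SD. PSTPIP2 lay between 32.1 and 68.9 CPM in the 4 libraries at 200 mg/kg and between 5.66 and 9.89 in the 4 controls.

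The proliferation list was called in microglia at 200 mg/kg against anti-gD (camera adjusted p = 6.39e-08; adjusted p = 0.571 with an estimated correlation), and 7 of its genes passed when adjusted over the list alone. TOP2A, the topoisomerase of dividing cells, stood at 61.9 ± 68.9 CPM against 11.6 ± 12.9. The chromatin regulator ATAD2 was at 75.8 ± 40.4 against 30.2 ± 11.3, the DNA polymerase POLQ at 27.4 ± 13.5 against 6.63 ± 2.46, and the histone methyltransferase EZH2 at 42.6 ± 30.5 against 15.9 ± 2.43. The summed list was 1236 ± 619 CPM against 732 ± 153, a difference within the spread between animals (exact p = 0.0857, adjusted p = 0.171). Most of the spread lay in library 3, at 2163 CPM against 897.5 to 953.3 in the other 3, and without it the difference was 198.8 instead of 503.7 CPM. MKI67, a marker of cycling cells, had too few UMIs for the test: 36 at 200 mg/kg, 5 in controls, 4 at 50 mg/kg and 4 at day 29.

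Microglia with at least 2 UMIs of genes of the G2 and M phases numbered 51 of 2126 at 200 mg/kg (2.40%) and 11 of 2357 in controls (0.467%). Of the 51, 37 came from library 3. In oligodendrocytes, which do not divide, the shares were 0.166% and 0.138% at a median depth of 1171 UMIs, close to that of microglia. Per library, the share in microglia was 2.05 ± 2.08% against 0.663 ± 0.636% (exact p = 0.229). This count leaves out ANLN and was chosen after the values per library were seen.

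**Figure D2:**
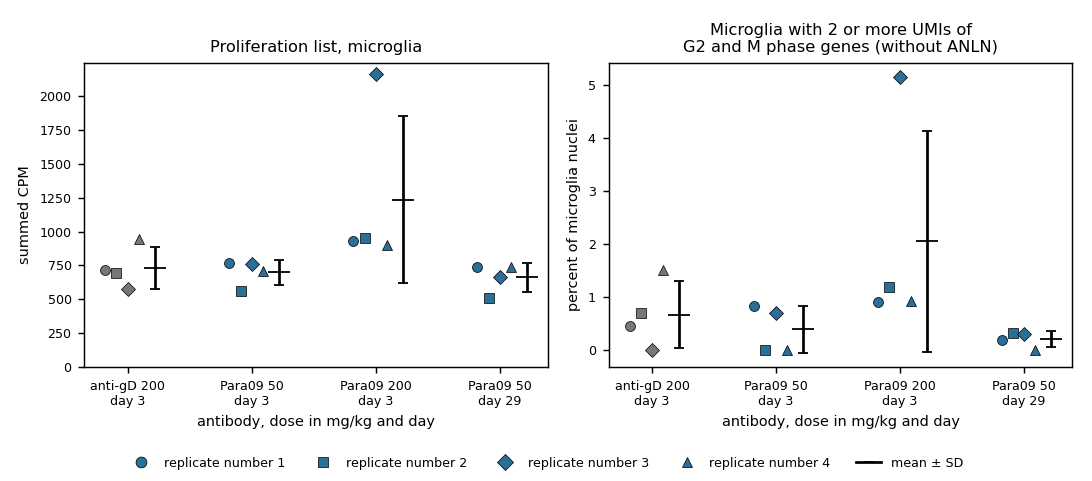
Summed CPM of the proliferation list in microglia, and the percentage of microglia with at least 2 UMIs of G2 and M phase genes other than ANLN, with a point for each library and bars for the group mean and SD. The library at 200 mg/kg with 2163 CPM stood apart from the other 3 of its group.

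The Fc receptor and complement list (adjusted p = 0.000198; adjusted p = 0.679 with an estimated correlation) had a median log2 difference of -0.51 at 200 mg/kg, and 0 of its genes passed when adjusted over the list alone. C1QB, a chain of the complement starter C1q, was at 878 ± 542 against 1717 ± 797 CPM, and the inhibitory Fc receptor FCGR2B at 117 ± 46.7 against 183 ± 26.7. The homeostatic list had a median of -0.33 (adjusted p = 0.00328; adjusted p = 0.679 with an estimated correlation), with 0 genes adjusted over the list alone. In it, the purine receptor P2RY12 was at 154 ± 51.8 against 238 ± 49.1 and the fractalkine receptor CX3CR1 at 690 ± 199 against 903 ± 103. Mitochondrial genes took 0.265 ± 0.214% of microglial UMIs at 200 mg/kg and 0.373 ± 0.184% in controls (exact p = 0.429). With that share as a covariate neither list was called. The mean of the homeostatic genes moved from -0.29 (SD 0.249 over genes) to -0.19 (SD 0.25), and the mean of the Fc receptor and complement genes moved from -0.49 (SD 0.292 over genes) to -0.23 (SD 0.278), with an adjusted p of 0.0508.

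The interferon response list had 10 of 15 members higher and a median of 0.25 (adjusted p = 0.0191; adjusted p = 0.679 with an estimated correlation). IFI44L was at 89.9 ± 25.2 CPM against 34.9 ± 14.1, and 1 gene of the list passed when adjusted over the list alone. The antigen presentation list had 9 of 11 lower and a median of -0.52 (adjusted p = 0.0369; adjusted p = 0.679 with an estimated correlation; 0 adjusted over the list alone). TAP2, a peptide transporter, had a log2 difference of -0.94 and the class II chaperone CD74 one of -0.57. The interferon call was lost without number 2 or 3 of Para09 200 mg/kg, the antigen presentation call without number 1 of anti-gD or number 1 or 4 of Para09 200 mg/kg (adjusted p up to 0.443 over 26 settings), and the homeostatic call without number 3 of anti-gD. The antigen presentation call was also lost with the replicate number as a block, without the low-count filter and with nuclei of at least 1000 genes. It was lost without the libraries numbered 4 and with the mitochondrial share as a covariate as well. TREM2 itself was at 229 ± 104 CPM against 250 ± 114, and its adaptor TYROBP had a log2 difference of -0.58. CSF1R was at -0.33, APOE at -0.29 and SPP1 at 0.73, all with an adjusted p of 1. IGF1, a growth factor of the disease-associated list, was at 129 ± 5.70 against 72.1 ± 11.3 CPM (adjusted p = 0.831), and CD163, a scavenger receptor of border macrophages, at 518 ± 86.9 against 343 ± 36.7 (adjusted p = 1).

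In the other cell types at 200 mg/kg, the gene that changed was CNTN3 (ENSMFAG00000045446), a neuronal adhesion protein, in oligodendrocytes. It rose from 8.66 ± 3.27 to 105 ± 62.1 CPM, a log2 difference of 3.81 (SE 0.589, adjusted p = 0.0392), and all 4 treated libraries lay above the controls. The gene was more abundant in excitatory neurons, at 476 ± 229 CPM in controls and 498 ± 218 at 200 mg/kg, and it was left out when genes over 5 times higher in other types were removed. Myelin genes were slightly lower in oligodendrocytes, with 12 of 13 below control and a median of -0.14 (adjusted p = 0.0417; adjusted p = 0.708 with an estimated correlation; 0 adjusted over the list alone). Mitochondrial genes took 0.486 ± 0.439% of oligodendrocyte UMIs at 200 mg/kg and 0.680 ± 0.397% in controls. CNTN3 was the only gene called by edgeR of 9394 tested in oligodendrocytes, where 194 had an unadjusted p under 0.05 and DESeq2 called 1. In astrocytes, oligodendrocyte precursors, both neuron classes and vascular nuclei, edgeR called 0 genes, with 141 to 301 at an unadjusted p under 0.05 and 0 by DESeq2. The CNTN3 call was lost without any one of numbers 1 to 4 of anti-gD, 1 to 3 of Para09 200 mg/kg, 1 and 4 of Para09 50 mg/kg day 3, or 1 and 3 of day 29 (adjusted p from 2.22e-06 to 1 over 26 settings). The myelin call was lost in 12 of 26 settings, among them omission of number 2 or 3 of anti-gD, number 1 or 4 of Para09 200 mg/kg, number 3 of Para09 50 mg/kg day 3, or number 4 of day 29 (adjusted p up to 0.627 over all settings).

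Para09 at 50 mg/kg was compared with anti-gD on day 3 to ask what the lower dose did. The control antibody was given at 200 mg/kg, so antibody and amount differ together here. Antigen presentation genes were lower in microglia, with 10 of 11 members below control and a median log2 difference of -0.81 (adjusted p = 0.616 with an estimated correlation). The class II gene HLA-DRA was at 26.7 ± 17.3 CPM against 95.7 ± 56.8 and CD74 at 110 ± 33.7 against 235 ± 137. Both genes also led the perivascular macrophage cluster, which made up 0.448 ± 0.267% of nuclei at 50 mg/kg against 0.665 ± 0.436% in controls (exact p = 0.486) and 0.754 ± 0.560% at 200 mg/kg. That share was highest among controls in number 1, at 1.29%, the library without which the call was lost, so that a part of macrophage RNA stays open. The border macrophage list in microglia had a median of -0.30. Genes of disease-associated microglia were lower as a group as well, with 13 of 15 below control and a median of -0.33 (adjusted p = 0.77 with an estimated correlation), and CTSL, a lysosomal protease, was at 28.9 ± 16.9 against 64.0 ± 6.12. In excitatory neurons, immediate early genes, which neurons switch on with activity, were lower, with 15 of 16 below control and a median of -0.19 (adjusted p = 0.679 with an estimated correlation). The summed list there was 254 ± 39.6 against 275 ± 31.0 CPM.

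The antigen presentation list was called at 50 mg/kg with an adjusted p of 0.00103 (adjusted p = 0.616 with an estimated correlation). The disease-associated list had 0.0371 as its adjusted p (adjusted p = 0.77 with an estimated correlation), and the immediate early list in excitatory neurons 0.00187 (adjusted p = 0.679 with an estimated correlation). In each, 0 genes passed when adjusted over the list alone. Mitochondrial genes took 0.285 ± 0.218% of microglial UMIs at 50 mg/kg and 0.373 ± 0.184% in controls, and 0.292 ± 0.181% against 0.529 ± 0.282% of excitatory neuron UMIs. EdgeR called 0 microglial genes, with 266 at an unadjusted p under 0.05, and DESeq2 called 1, LILRA4, at 5.67 ± 4.08 CPM against 44.6 ± 15.6 (log2 difference -2.69, SE 0.454, adjusted p = 0.105 by edgeR). CLDN1, a tight junction protein, had 0 of 2023242 UMIs at 50 mg/kg, which allows up to 1.48 CPM over the group, and 53 UMIs in controls (adjusted p = 0.739). PSTPIP2 was at 25.4 ± 5.26 CPM, a log2 difference of 1.69 (SE 0.454) that did not pass. RGS6 had a log2 difference of 1.10 (SE 0.266) and the opsin gene RRH one of 2.45, both with an adjusted p of 1. TREM2 was at -0.39, TYROBP at -0.36, CSF1R at -0.17, P2RY12 at -0.26, APOE at -0.27 and SPP1 at -0.74, none past the test. In the other 6 types edgeR called 0 genes, with 111 to 293 at an unadjusted p under 0.05 and 0 by DESeq2. The antigen presentation call was lost without number 1 of anti-gD (adjusted p up to 0.0959 over 26 settings), the immediate early call without number 3 of either group (up to 0.767), and the disease-associated call without number 1 or 2 of anti-gD, number 3 or 4 of Para09 50 mg/kg day 3 or number 1 of day 29 (up to 0.48). The last was lost with the mitochondrial share as a covariate as well, where its mean over genes moved from -0.30 (SD 0.373) to -0.17 (SD 0.389).

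Both Para09 doses were compared on day 3. Proliferation genes were higher in microglia at 200 than at 50 mg/kg, with 12 of 13 members above and a median log2 difference of 1.30 (adjusted p = 0.571 with an estimated correlation), and interferon response genes were higher, with 11 of 15 above and a median of 0.36 (adjusted p = 0.617 with an estimated correlation). Fc receptor and complement genes were lower at the higher dose, with 9 of 10 below and a median of -0.28 (adjusted p = 0.77 with an estimated correlation). In astrocytes, genes of reactive astrocytes were higher, with 10 of 12 above and a median of 0.12 (adjusted p = 0.616 with an estimated correlation). The acute phase gene SERPINA3 of that list was at 32.4 ± 26.6 CPM against 4.73 ± 5.62.

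The proliferation list had an adjusted p of 6.27e-08 between the doses (adjusted p = 0.571 with an estimated correlation), and 9 of its genes passed when adjusted over the list alone. The interferon response list had 0.00367 (adjusted p = 0.617 with an estimated correlation), the Fc receptor and complement list 0.0369 (adjusted p = 0.77 with an estimated correlation) and the reactive astrocyte list 0.0369 (adjusted p = 0.616 with an estimated correlation), with 0, 0 and 1 genes adjusted over the list alone. The summed proliferation list was 537.3 CPM higher at 200 mg/kg, with all 4 libraries above the 4 at 50 mg/kg, which averaged 698 ± 93.6 (exact p = 0.0286, adjusted p = 0.114). Without library 3 of 200 mg/kg the difference was 231.3 CPM. TOP2A was at 61.9 ± 68.9 against 3.58 ± 3.51 CPM (log2 3.80, SE 0.842, adjusted p = 0.705) and CD163 at 518 ± 86.9 against 269 ± 51.4 (log2 0.93, SE 0.199, adjusted p = 0.705). RHOQ had a log2 difference of -0.73, FAM114A1 one of -0.82 and APOLD1 one of 2.40, none past the test. IFI44L was at 89.9 ± 25.2 against 46.2 ± 12.9 CPM, and IFI6 had a log2 difference of 1.29. TREM2 was at 0.19, TYROBP at -0.22, CSF1R at -0.16, P2RY12 at -0.41, APOE at -0.03, SPP1 at 1.47 and CD74 at 0.66. EdgeR called 0 microglial genes, with 334 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 genes in the other 6 types, with 139 to 319 and 0 by DESeq2. The Fc receptor and complement call was lost without number 1 or 4 of Para09 200 mg/kg or number 2 or 3 of Para09 50 mg/kg (adjusted p up to 0.441 over 26 settings), and the reactive astrocyte call without number 4 of Para09 200 mg/kg or number 1 or 3 of Para09 50 mg/kg (up to 0.305).

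Day 29 was compared with day 3 at 50 mg/kg to ask how the state of the tissue differed later. In oligodendrocytes all 13 myelin genes were lower at day 29, with a median log2 difference of -0.26 (adjusted p = 0.616 with an estimated correlation), and CNP, a myelin enzyme, was at 185 ± 51.9 against 287 ± 80.5 CPM. Immediate early genes were lower in excitatory neurons, with 12 of 16 below and a median of -0.68 (adjusted p = 0.679 with an estimated correlation), and in inhibitory neurons, with 12 of 15 below and a median of -0.40 (adjusted p = 0.708 with an estimated correlation). The summed list in excitatory neurons differed little, at 233 ± 5.33 against 254 ± 39.6 CPM, and all 4 day 29 libraries (229 to 241) lay within the day 3 range (203 to 299). The transcription factor EGR1 was at 8.10 ± 3.37 against 19.4 ± 11.1 CPM in excitatory neurons. No microglial list was called, and TREM2 was at 197 ± 89.2 against 186 ± 95.4 CPM in microglia.

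The myelin list had an adjusted p of 0.000696 (adjusted p = 0.616 with an estimated correlation), the immediate early list 0.00148 in excitatory neurons (adjusted p = 0.679 with an estimated correlation; 1 gene adjusted over the list alone) and 0.0181 in inhibitory neurons (adjusted p = 0.708 with an estimated correlation). Adjusted over the list alone, 0 genes passed in the myelin list and 0 in inhibitory neurons. At day 29 and day 3 mitochondrial genes took 0.359 ± 0.344% and 0.424 ± 0.302% of oligodendrocyte UMIs, 0.274 ± 0.150% and 0.292 ± 0.181% in excitatory neurons, and 0.356 ± 0.201% and 0.429 ± 0.266% in inhibitory neurons. EdgeR called 0 microglial genes, with 166 at an unadjusted p under 0.05 and 0 by DESeq2. In the other 6 types edgeR called 0, with 143 to 544, and DESeq2 called 1, the protease gene CASP6 in excitatory neurons (log2 0.56, adjusted p = 0.00403 by DESeq2). In microglia, the peptidase gene NAALAD2 was at 29.4 ± 6.23 against 89.1 ± 24.3 CPM, ZNF385D had a log2 difference of 2.14, MEIS2 one of -2.08 and LRP6 one of -0.66, all with an adjusted p of 1. TYROBP was at -0.15, CSF1R at 0.03, P2RY12 at -0.11, APOE at -0.47, SPP1 at -0.80 and CD74 at 0.85. The myelin call was lost without number 2 of Para09 50 mg/kg day 3 (adjusted p up to 0.0688 over 26 settings), and the inhibitory neuron call without number 1 of day 29 or number 4 of day 3 (up to 0.567). Without the 4 libraries numbered 4, the call in excitatory neurons was lost as well (adjusted p up to 0.129).

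Day 29 was also set against the day 3 controls, a comparison in which treatment, amount of antibody and day cannot be separated. Immediate early genes were lower in excitatory neurons, with 13 of 16 below and a median log2 difference of -1.04 (adjusted p = 0.571 with an estimated correlation), and in inhibitory neurons, with 12 of 15 below and a median of -0.66 (adjusted p = 0.679 with an estimated correlation). The summed list in excitatory neurons differed by less, at -0.24 on the log2 scale (exact p = 0.0571). All 13 myelin genes were lower in oligodendrocytes, with a median of -0.28 (adjusted p = 0.616 with an estimated correlation), and CNP had a log2 difference of -0.75. In microglia, homeostatic genes (12 of 13 below, median -0.20), disease-associated genes (12 of 15 below, median -0.35) and lysosomal genes (18 of 25 below, median -0.23) were lower (adjusted p = 0.706, 0.708 and 0.715 in this order with an estimated correlation). On the summed disease-associated list number 2 of day 29 was at 6452 CPM, above the control mean of 5398 ± 1478, and the other 3 were at 2691 to 3137. SPP1, the gene of osteopontin, was at 28.0 ± 26.2 against 105 ± 110 CPM and the lysosomal PSAP had a log2 difference of -0.53.

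The immediate early list had an adjusted p of 1.25e-07 in excitatory neurons (adjusted p = 0.571 with an estimated correlation; 1 gene adjusted over the list alone) and 0.00144 in inhibitory neurons (adjusted p = 0.679 with an estimated correlation). The myelin list had 0.000109 (adjusted p = 0.616 with an estimated correlation). In microglia the homeostatic list had 0.0266, the disease-associated list 0.00915 and the lysosome list 0.0188 (adjusted p = 0.706, 0.708 and 0.715 with an estimated correlation). Mitochondrial genes took less of the UMIs at day 29 than in controls, on average, in excitatory neurons (0.274 ± 0.150% against 0.529 ± 0.282%), inhibitory neurons (0.356 ± 0.201% against 0.536 ± 0.269%), oligodendrocytes (0.359 ± 0.344% against 0.680 ± 0.397%) and microglia (0.269 ± 0.198% against 0.373 ± 0.184%). In the 3 microglial lists, in the myelin list and in inhibitory neurons, 0 genes passed when adjusted over the list alone. Of 22 excitatory clusters, 10 drew over 50% of their nuclei from 1 library. EdgeR called 0 microglial genes, with 325 at an unadjusted p under 0.05, and DESeq2 called 2. These were TSBP1, at 55.9 ± 19.9 against 9.12 ± 3.04 CPM (log2 2.51, SE 0.485), and the iron exporter SLC40A1, at 35.9 ± 11.1 against 110 ± 7.74 (SE 0.322), each with an adjusted p of 0.492 by edgeR. LILRA4 was at -1.82 (SE 0.39) against the same 4 controls that served in the other comparisons, ROR2 at -1.60 and the clock gene NR1D2 at -0.97, none past the test. TREM2 was at -0.40, TYROBP at -0.52, CSF1R at -0.15, P2RY12 at -0.37, APOE at -0.74 and CD74 at -0.38. In the other 6 types edgeR called 0, with 161 to 834, and DESeq2 called 1, PRCP in astrocytes (log2 -0.78, adjusted p = 0.00882 by DESeq2). With the mitochondrial share as a covariate the 3 microglial calls were lost, as the means over genes moved toward 0: from -0.22 (SD 0.158) to -0.13 (SD 0.161) for the homeostatic list, -0.38 (SD 0.413) to -0.21 (SD 0.427) for the disease-associated list and -0.20 (SD 0.287) to -0.12 (SD 0.267) for the lysosome list. The SD over genes does not measure how exactly a mean is known, so it cannot show whether these moves exceed chance. The medians moved to -0.14 and -0.09 for the last 2 lists, but the homeostatic one did not shrink (-0.20 and -0.22), so that the losses leave the cause open. All 3 calls were also lost without number 4 of day 29, the homeostatic one also without number 1 of day 29 or 1 or 3 of anti-gD, the disease-associated one without number 2 of anti-gD, and the lysosome one without number 3 of day 29 or 1 or 2 of anti-gD (adjusted p up to 0.294 over 26 settings).

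The remaining list tests did not pass. In microglia, adjusted p-values over the 5 comparisons ran from 0.255 to 0.854 for lipid handling, 0.163 to 0.937 for cholesterol synthesis, 0.105 to 0.74 for inflammatory chemokines and cytokines, 0.482 to 0.937 for TREM2 receptor signalling, 0.395 to 0.906 for growth and metabolism and 0.105 to 0.563 for border macrophage genes. In oligodendrocytes cholesterol synthesis ran from 0.313 to 0.858. Immediate early genes ran from 0.0725 to 0.74 in astrocytes, 0.0725 to 0.515 in oligodendrocytes, 0.255 to 0.74 in oligodendrocyte precursors and 0.255 to 0.937 in vascular nuclei. Heat shock genes ran from 0.105 to 0.997 over all types. Of the 145 tests, 22 were called with the preset correlation and 0 with an estimated one or by fry. The median, mean and test of a list differed in sign in 18 tests, 0 of them called, such as the border macrophage list at 200 mg/kg against anti-gD, with a median of -0.14 and a mean of 0.11.

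Cell type shares were compared to ask whether the tissue held more microglia after treatment. Microglia made up 7.62 ± 2.13% of nuclei in controls, 6.42 ± 2.52% at 50 mg/kg, 6.20 ± 2.03% at 200 mg/kg and 8.11 ± 0.914% at day 29. No difference exceeded the spread between animals, with exact p = 0.343 for 200 mg/kg and 0.486 for 50 mg/kg against anti-gD, 0.914 between the doses and 0.286 between the days. Astrocytes made up 10.8 ± 2.73% at day 29 against 7.34 ± 0.847% at day 3 of 50 mg/kg, with all 4 libraries above (exact p = 0.0286, adjusted p = 0.731). Excitatory neurons were at 31.1 ± 9.96% against 48.0 ± 4.24% (exact p = 0.0571). Number 1 of day 29 was at 19.4%, without 1141 of its nuclei (17.9%) in an unnamed cluster with 4 excitatory markers. None of the 32 share tests passed after adjustment.

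**Figure D3:**
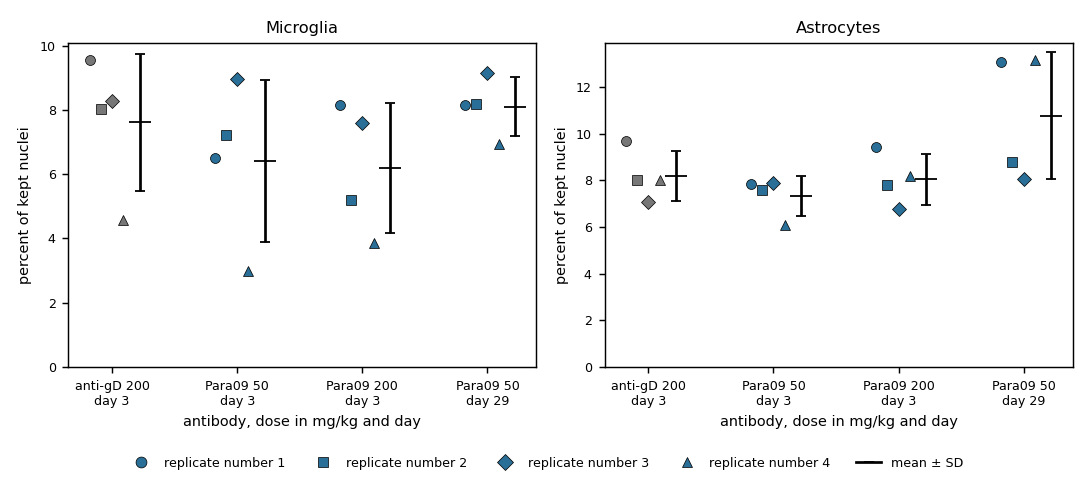
Microglia and astrocytes as percentages of kept nuclei, with a point for each library and bars for the group mean and SD. The mean microglia share lay between 6.20% and 8.11% in the 4 groups.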

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

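The counts over other splits, the relation to the mitochondrial share, the mitochondrial covariate, the comparison within excitatory clusters and the count of day 29 controls were chosen after the results were seen, while the tests of RNA from other types and of doublets were written before.

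The proliferation list was higher in microglia at 200 mg/kg than in anti-gD microglia. RNA from glia other than microglia, neurons and vascular nuclei is argued against. The summed list over these nuclei differed by 0.034 on the log2 scale (415 ± 70.7 against 405 ± 67.6 CPM, exact p = 0.771), against 0.77 in microglia. Excitatory neurons held most UMIs of that sum. By type, the difference ran from -0.263 in vascular nuclei to 0.251 in oligodendrocyte precursors. Perivascular macrophages and lymphocytes were not in the sum, so RNA from them was not tested. Doublets with oligodendrocyte precursors, which divide in the adult brain, are argued against as well, since precursor markers in microglia had a ratio of 1.08 between the groups (60.1 ± 29.9 against 55.6 ± 14.1 CPM, exact p = 0.857), far below the 10600 CPM in precursors. Chance could not be excluded, since 2 of the 35 splits of the 8 libraries gave a camera p as small (8.81e-10 for the real split, 7.9e-10 for the strongest other). More dividing microglia at 200 mg/kg may account for the pattern, as a hypothesis: the list was called under 26 processing settings, omission of library 3 included, with the preset correlation (highest adjusted p 0.00365) but not with an estimated one (adjusted p = 0.571), and without library 3 the summed level differed by 198.8 CPM.

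The Fc receptor and complement list was lower in microglia at 200 mg/kg with the preset correlation, but was not called with an estimated one (adjusted p = 0.679). Less cytoplasmic RNA in the nuclei is a candidate explanation: over all 16 libraries, as deviations from group means, the list level followed the mitochondrial share with r = 0.858 and rho = 0.83 (permutation p = 0.00025 and 0.00066, 100000 permutations). Without the 2 libraries farthest from the median r was 0.809, and without the libraries numbered 4 it was 0.805. Between the doses, however, the list was also lower at 200 mg/kg while mitochondrial shares were close (0.265 ± 0.214% against 0.285 ± 0.218%). With the share as a covariate its mean there moved from -0.295 to -0.251, and the call at the preset correlation stayed. The share thus took up little of the dose difference, a call kept in 20 of 26 settings. The permutations treated the 16 libraries as independent, but libraries with the same number deviated together in microglia. Median mitochondrial shares per library were 0.0266 to 0.0889% in those numbered 4 and 0.256 to 0.348% in those numbered 2. The permutation p-values are therefore likely too small. Chance could not be excluded either, since 8 of 35 splits gave a camera p as small (6.81e-06 for the real split, 2.84e-10 for the strongest other). An effect of the antibody stays open and untested apart from these.

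Immediate early genes were lower in excitatory neurons at day 29 than in controls. Of 35 splits, 1, the real one, gave a camera p as small (2.59e-09, against 5.98e-09 for the strongest other), but the list was picked among 145 tests for its small p and lost its call with an estimated correlation (adjusted p = 0.571), so that chance stays open. With the mitochondrial share as a covariate the list kept a camera adjusted p of 5.22e-06 at the preset correlation. That p does not show whether the difference stayed as large, so less cytoplasmic RNA remains possible. A different makeup of the excitatory nuclei stays open: within the 5 clusters with at least 2 libraries per group the median log2 ratio was -0.294 (from -0.986 to 0.253, 4 of 5 below 0), and within the 2 clusters with at least 3, the rule first tried, it was -0.673. The mean over the 5 clusters had an SE of 0.205, but the clusters share animals, so it does not measure the spread between animals. Antibody, day and handling cannot be told apart, because 0 control libraries were from day 29; the summed list was 233 ± 5.33 CPM against 275 ± 31.0 (exact p = 0.0571).

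For the counts above 0 of called genes and lists, chance could not be excluded. In microglia at 200 mg/kg against anti-gD, 2 of 35 splits called as many genes (1 for the real split, 1 for the highest other), 5 did in the other types (1 and 15), and 10 called as many lists (6 and 11). As many lists were called in 20 splits at 50 mg/kg against anti-gD (2 and 7), 15 between the doses (4 and 12), 14 between the days (3 and 8) and 8 at day 29 against anti-gD (6 and 9). Lists were adjusted here within each comparison, which left 2 calls in place of 3 at 50 mg/kg against anti-gD. Where the real count was 0, all 35 splits reach it by construction, which tests nothing. The highest other count was then 1 in microglia and 68 in other types at 50 mg/kg against anti-gD, 46 in microglia between the doses, 1 in microglia and 942 in other types between the days, and 1 in microglia at day 29 against anti-gD. Splits that called 46, 68 and 942 genes point to a structure of the samples other than the groups. The split with 68 genes set numbers 1 and 4 of both groups against numbers 2 and 3, as did that with 15 genes at 200 mg/kg. Those with 46 and 942 genes did not follow the numbers in this way. The counts over 35 splits may therefore reflect the numbers as well as chance.

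In 8 of 124 groups of 4 libraries, 1 library stood apart from the other 3, where chance gives about 1 in 20. The astrocyte share was 6.079% in number 4 of Para09 50 mg/kg day 3 against 7.583 to 7.863% in the others. The oligodendrocyte share was 4.378% in number 1 of that group against 11.44 to 12.73%. In microglia of number 3 of Para09 200 mg/kg, the proliferation list stood at 2163 CPM, and its G2 and M phase genes at 569.1 CPM against 114 to 123.5. In microglia of number 2 of day 29, the disease-associated list was at 6452 CPM against 2691 to 3137 and the lipid handling list at 4743 against 2227 to 2382. The TREM2 receptor signalling list was at 5220 CPM in number 4 of Para09 50 mg/kg day 3 against 5842 to 5895. Myelin genes in microglia were at 2833 CPM in number 4 of anti-gD against 720.4 to 975.3.

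Some counts of nuclei outside the comparisons were above those of the controls, and those given here are not all of them. Number 1 of day 29 held 1141 nuclei of an unnamed cluster of 1287 with 4 excitatory markers, of which controls held 0. Number 3 of day 29 held 82 of 95 nuclei of a cluster with the cilia genes CFAP299, HYDIN and SPAG17, of which controls held 9, all in number 4; as shares the 2 libraries were alike, at 0.768% and 0.625% of their nuclei. Lymphocyte nuclei numbered 28 at 200 mg/kg and 10 in controls.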

How the results depend on the processing

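The mitochondrial share as a covariate and the list levels without ANLN or RAD51B were chosen after seeing the data. So were the list tests under all alternatives except an estimated correlation, the block and the omission of the libraries numbered 4. Lists called kept their side of the threshold in 494 tests under alternatives and lost it in 100. Of 20267 values of named genes under alternatives, 27 moved past the threshold, 25 fell back from it and 298 changed sign. Nearly all of these values belonged to genes that were not called and so could not fall back. The 25 were those of the called genes, with PSTPIP2 lost in 11 of 26 settings and CNTN3 in 14 of 26. In microglia at 200 mg/kg against anti-gD, 2 genes were called with DESeq2, 2 without the low-count filter, 2 with the replicate block and 2 without doublet removal, and 0 with nuclei of at least 1000 genes, 0 with libraries of at least 50 nuclei and 0 with the mitochondrial covariate. At 50 mg/kg, 1 was called with DESeq2, 2 without the filter and 1 with the block. Between the doses 1 (TOP2A) was called without the filter. At day 29 against anti-gD, 2 were called with DESeq2, 3 without the filter and 4 with only the groups compared. In other types at 200 mg/kg, 0 were called with only the groups compared, 0 without doublet removal, 0 with nuclei of at least 1000 genes, 0 without genes higher in other types and 3 with the mitochondrial covariate. At 50 mg/kg, 1 (IGKC) was called without the filter and 1 (C17orf64) with the mitochondrial covariate. Between the days, 1 (CASP6) was called with DESeq2 and 1 (IGKC) without the filter.

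The proliferation level was higher at 200 mg/kg than in anti-gD by 420.9 CPM without RAD51B and by 503.4 CPM without ANLN. Each had an exact p of 0.0286, the smallest possible, which was not adjusted. The planned list had 0.0857 before and 0.171 after adjustment. With its G2 and M phase genes only, the groups overlapped, at 230.8 ± 225.5 against 88.3 ± 54.3 CPM. Number 3 of Para09 200 mg/kg was at 569.1 CPM. The others of its group, at 114 to 123.5, lay below the highest control, at 162.3. The microglia share between the doses turned to 0.180 with nuclei of at least 1000 genes, and that between the days to -2.874 as a share of non-neuronal nuclei. Lists called numbered 14 with nuclei of at least 1000 genes, 13 with the mitochondrial covariate and 0 with an estimated correlation. The cause was not tested for these changes, apart from the smaller number of nuclei, libraries or genes where a setting removes them.

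With each library left out in turn, microglial genes called ran from 0 to 2 at 200 mg/kg against anti-gD, 0 to 1 at 50 mg/kg, and 0 to 0 in the other 3 comparisons. Genes in other types ran from 0 to 1 at 200 mg/kg and 0 to 0 otherwise. The microglia share difference ran from -2.426 to -0.632 at 200 mg/kg, -2.203 to -0.0458 at 50 mg/kg, -1.371 to 0.630 between the doses and 0.538 to 2.539 between the days. The sign between the doses turned without number 2 (0.0489) or 3 (0.630) of Para09 50 mg/kg or number 2 (0.115) or 4 (0.561) of Para09 200 mg/kg. The difference in the proliferation level at 200 mg/kg against anti-gD ran from 198.8 to 612.2 CPM (exact p from 0.0571 to 0.257), and lists called from 18 to 29.

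Libraries with the same replicate number deviated together in microglia in 18 of 24 pairs (r over 0.1, lowest 0.005), and all 16 correlated best with a library of their own number. Such pairs numbered 22 in inhibitory neurons, 22 in oligodendrocytes, 19 in astrocytes, 18 in oligodendrocyte precursors and 17 in excitatory neurons, but 8 of 21 in vascular nuclei. The structure comes from the data, and the labels do not say what the number stands for. Neither the main fits nor the exact permutation tests took it into account. The number of list calls was 26 with the block and 25 without the libraries numbered 4. The block ended the antigen presentation call at 200 mg/kg against anti-gD (adjusted p = 0.12). It added disease-associated (0.0158) and reactive astrocyte genes (0.0349) there, lysosomal genes at 50 mg/kg (0.0363), chemokines and cytokines between the days (0.0432), and Fc receptor and complement genes at day 29 against anti-gD (0.00426). None of these lists was called with an estimated correlation, which was used without the block. At this depth, with 8507 microglial nuclei, changes of 2-fold or less were mostly not detectable gene by gene, and larger ones could be missed.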

Other observations

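Lymphocyte nuclei, named from T cell markers, were more frequent at 200 mg/kg than in controls, at 0.0947 ± 0.0246% of nuclei against 0.0315 ± 0.0245%, with all 4 libraries above (exact p = 0.0286, adjusted p = 0.114). This comparison was chosen after the data were seen. They numbered 10 at 50 mg/kg and 39 at day 29, of which 25 were in number 1, and the 3 other comparisons tested gave exact p = 0.4 for 50 mg/kg against anti-gD, 0.257 between the doses and 0.2 between the days. Astrocytes at 200 mg/kg held SERPINA3, an acute phase gene, at 32.4 ± 26.6 CPM against 4.44 ± 3.05 in controls (log2 2.89, SE 0.696, adjusted p = 1), and CHI3L1, a secreted marker of reactive astrocytes, at 55.3 ± 28.8 against 23.3 ± 19.2 CPM. Neither passed the test, and the reactive astrocyte list there had a median of -0.01 and a mean of 0.40.

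Among the unnamed clusters, 178 nuclei carried BCAS1, TNS3, ENPP6 and GPR17, genes of oligodendrocyte precursors on the way to myelination. Their mean share was 0.131% in controls, 0.163% at 50 mg/kg, 0.261% at 200 mg/kg and 0.203% at day 29. A cluster of 475 nuclei with mitochondrial genes and GFAP had mean shares of 0.488 ± 0.424%, 1.58 ± 2.75%, 0.949 ± 1.32% and 0.431 ± 0.182% in the same order. The higher means came from the small libraries numbered 4, with 5.71% at 50 mg/kg against 0.147 to 0.251% in the other 3, and 2.92% at 200 mg/kg against 0.210 to 0.425%. No test was run on these shares.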
